A study of Mus musculus with 33 samples.

How the data were processed

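Gene expression was measured in 33 mouse libraries, each with 1 table of counts that the authors deposited. Per the file headers, the values are unique read counts per RefSeq transcript, with library totals from 427556 to 30609013. They are whole numbers except for 15 values in all. The deposited tables that hold such values were treated as estimated counts and rounded to whole numbers. Per the labels' protocols, total RNA was extracted, mRNA was isolated and single-stranded cDNA was made, and cDNA in the SMART-seq libraries was amplified with 13 cycles. The aligner, the counting rule, the RefSeq release and the genome build are not given in the sources used here, so no coordinates are printed. If unique reads leave out those that match several transcripts, genes with isoforms of shared sequence or near-identical copies, such as ribosomal protein genes and tubulins, have too few counts. Strand use is not known either, so overlapping and antisense genes cannot be separated. Of 26566 transcripts, 25857 were named through a RefSeq gene table and 150 through GENCODE's RefSeq table; the 559 without a symbol stayed under their own identifier. Transcript counts were summed to 21844 genes, 3080 of them with more than 1 transcript.

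Groups and replicate numbers follow the labels, and no group has more than 2 libraries. Every pair of libraries but the SFM pair is labelled as technical replicates, and nothing says that the SFM libraries came from separate cultures. Apart from SFM, p-values therefore set differences between samples against technical spread, and n = 2 is 1 sample measured 2 times. A group with 1 library is assumed to vary like the other groups in its fit. Samples, gene lists, the rule for named genes, and the tests and alternatives other than those said to be chosen later were fixed before the data were examined. Counts were tested with edgeR 4.0.16 in R 4.3.3: genes were kept with filterByExpr by group (minimum count 10, minimum total 15), scaled by TMM, and fitted with robust quasi-likelihood models, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. The dose trend used SFM, AA3, AA15 and AA100 as equally spaced steps; the comparisons with SFM used all 7 libraries of the dose set, and the method comparisons each method's own libraries. Differences between methods came from a joint fit of 10 libraries, the dilution comparisons from all 12 libraries of the series, and the primer sets were set against the mean of the 1 ng and 100 pg libraries. Values after ± are standard errors of a log2 change, or SDs where n is given, and CPM are TMM-scaled unless stated otherwise.

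Gene lists were tested with camera in limma 3.58.1, with a preset inter-gene correlation of 0.01 and again with an estimated one, over the lists of a comparison with at least 3 tested genes. Lists drawn by symbol pattern for replication-dependent histones and mitochondrially encoded genes matched 0 symbols and could not be tested. Histone genes under other symbols, such as H2ac23, are among the genes measured. Named genes are up to 4 members of each list with the largest change among those tested, and the 5 largest rises and falls past the threshold with at least 50 counts in the higher group and the same direction in every pair of libraries. This left out unnamed models, pseudogenes and ribosomal protein copies; in the dilution series only the latter part was used. A selection of these is printed. Folds against a group at 0 counts use a floor of 3 counts over the group. Ribosomal protein shares use 85 genes, with Wilson 95% intervals from scipy 1.17.1; intervals and floors cover counting error only, since amplified reads are not independent molecules. Detection was compared after thinning each library to 427556 counts, and replicate spread over genes with a mean of at least 10 counts. Random lists for comparison were matched on expression in 20 bins and drawn 10000 times, and sequence shared between genes was measured in 32-base words of the reference transcripts. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures.

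The tests were tried on simulated data, with counts drawn from the real means and 200 genes changed. For the dose trend over 12102 genes, 23.9%, 92.5% and 93.9% of genes changed 2-, 4- and 8-fold per dose step were recovered. Of its calls 1.4% were false, and smaller changes per step were not simulated. For AA15 against SFM over 12180 genes none of the genes changed 2-, 4- or 8-fold was recovered. An absence of calls there therefore carries no information about stability. In the method comparisons the recovery was 91%, 92.5% and 97% for standard RNA-seq (12605 genes), 9%, 40.3% and 63.6% for DP-seq (11631 genes) and 19.4%, 43.3% and 65.2% for SMART-seq (11453 genes), with 5.1%, 9.6% and 7.6% of calls false. The simulated spread came from each fit itself, and so from technical replicates, which for standard RNA-seq are the 2 AA3 libraries alone. These recoveries therefore do not rank the methods or give their power between separate samples. For the difference between DP-seq and standard RNA-seq (14072 genes) the recovery was 0%, 7.5% and 21.2%. It was 0%, 0% and 9.1% at 100 pg and 0%, 0% and 7.6% at 1 pg (10817 genes), and 47.8%, 77.6% and 86.4% for primer set 1 (11559 genes), with 9.0% of calls false. Alternatives were DESeq2 size factors, no filter on low counts, DESeq2 1.42.0's Wald test, each library left out in turn, the replicate number as a block, other codings of the dose, fits of fewer or more libraries, thinned counts, and other count minimums, prior counts and ribosomal gene definitions. The paired-end library enters no edgeR or DESeq2 test.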

Results

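Mouse embryonic stem cells were grown without serum as embryoid bodies, which are aggregates of differentiating cells. The cells were dispersed on day 2 and then received activin A, a TGF-β family ligand that signals like Nodal, or SB-431542, an inhibitor of the activin, Nodal and TGF-β type I receptors, until day 4. Most libraries were made by DP-seq, which amplifies cDNA with a defined collection of heptamer primers. Standard RNA-seq and SMART-seq, which amplifies full-length cDNA from small samples, were run for comparison. The dose set held 2 libraries of the untreated serum-free control (SFM), 1 of SB-431542 (SB), 1 of activin at 3 ng/mL (AA3), 2 at 15 ng/mL (AA15) and 1 at 100 ng/mL (AA100). These libraries held 13053122 to 15707808 counts. A dilution series of AA3 mRNA had 2 DP-seq libraries at each of 10 ng, 1 ng, 100 pg, 50 pg, 10 pg and 1 pg, with 427556 to 10387268 counts. The method set held standard RNA-seq from 20 ng, with 2 AA3 and 1 AA100 libraries of 10389043 to 10738438 counts. It also held DP-seq from 50 pg, with 1 AA3 and 2 AA100 libraries of 10678979 to 13389156 counts, and SMART-seq from 50 pg, with 2 libraries of each of 25897343 to 30609013 counts. Primer sets 1, 2 and 3 were each used for 1 library of 500 pg AA3 mRNA, with 5019740 to 5996577 counts. A paired-end DP-seq library came from 100 pg. Every pair of libraries but the SFM pair is labelled as technical replicates, so its spread is technical.

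The first question was which genes follow the activin dose. Across SFM, AA3, AA15 and AA100, 18 genes rose and 30 fell of 12102 tested (edgeR quasi-likelihood test of a slope over 4 equally spaced steps, 6 libraries, Benjamini-Hochberg adjusted). Mixl1, a homeobox gene of the primitive streak, rose by 1.88 ± 0.21 log2 units per step (adjusted p = 0.0287). It stood at 4.08 ± 1.04 CPM (counts scaled to the library total; SD, n = 2) in SFM, 18.0 in AA3, 82.6 ± 6.85 (n = 2) in AA15 and 139 in AA100. Cer1, which encodes a secreted Nodal, BMP and Wnt antagonist of the anterior endoderm, rose from 38.7 ± 11.8 CPM in SFM to 712 in AA100 (slope 1.35 ± 0.15, adjusted p = 0.0287). Lhx1, a LIM homeobox gene of the streak and its anterior derivatives, went from 7.62 to 127 CPM, and Evx1, a homeobox gene of the posterior streak, from 16.1 ± 6.57 to 153 CPM. Their adjusted p-values were 0.0287 and 0.0456. Large called rises outside these lists included Foxq1, a forkhead transcription factor gene (slope 1.72 ± 0.14), and Isg15, an interferon-induced ubiquitin-like modifier gene (1.48 ± 0.19). Dpf3, a gene of the BAF chromatin remodelling complex, stood at 0.106 CPM (3 counts) in SFM and 7.83 CPM in AA100 and was also called.

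Among the called falls were 4 of 27 neuroectoderm genes. Pax6, a transcription factor gene of neural progenitors, fell from 313 ± 210 CPM in SFM to 14.3 in AA3, 4.38 ± 0.587 in AA15 and 1.57 in AA100 (slope −2.68 ± 0.33, adjusted p = 0.0352). Lhx2, a forebrain LIM homeobox gene, went from 57.7 ± 35.2 to 0.313 CPM, and Wnt8b, a forebrain Wnt gene, from 93.6 ± 55.1 to 0.313 CPM. Fezf1, a forebrain zinc finger gene, and Neurog2, a proneural gene, had 0 counts in AA100, at least 73.2-fold and at least 26.5-fold lower than in SFM with the floor of 3 counts over the group. Foxd4, a forkhead gene of the neural plate, and Ptn, which encodes the growth factor pleiotrophin, fell with slopes of −1.59 ± 0.17 and −1.42 ± 0.19. Edn1, which encodes endothelin-1, was called lower too, with 18.5 CPM in SFM and 2 counts in AA100. The call rested on single libraries. Without SFM replicate 2, 693 genes passed, without SFM replicate 1 only 2, and without AA15 replicate 1 or AA15 replicate 2 none did in edgeR (893 and 886 at unadjusted p under 0.05). DESeq2 called 469 over all libraries. The coding of the dose moved the count as well, to 196 with SB as the lowest step and 18 with log2 of dose plus 1. With the replicate number as a block it was 0 in edgeR (1039 at unadjusted p under 0.05).

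By list, 3 of 18 measured primitive streak genes rose and 0 fell (12 and 0 adjusted over the list alone), with a median slope of 0.94. For this list limma's camera gave an adjusted p of 2.1e-13, and adjusted p = 0.0206 with an estimated correlation. Of 20 definitive and anterior endoderm genes 1 rose (11 adjusted over the list alone; median 0.70, adjusted p = 3.1e-13; adjusted p = 0.0400 with an estimated correlation). The Activin/Nodal targets and feedback list had no member past the test over all genes, but 10 of 18 rose and 1 fell adjusted over the list alone (median 0.80, adjusted p = 2.2e-07; adjusted p = 0.0315 with an estimated correlation). Its members Lefty1, a Nodal antagonist gene, and Nodal had slopes of 1.86 ± 0.33 and 1.57 ± 0.44 (adjusted p = 0.0829 and 0.225), and Pmepa1, a feedback inhibitor gene of TGF-β signalling, one of 1.33 ± 0.34 (0.193). Of 27 neuroectoderm genes 4 fell and 0 rose (13 and 0 adjusted over the list alone; median −0.67, adjusted p = 1.4e-10; adjusted p = 0.0550 with an estimated correlation). Rax and Hes5, genes of the eye field and of Notch signalling, had slopes of −1.92 and −1.63 without passing. Among endoderm and streak genes that did not pass, Gsc, a homeobox gene of the anterior streak, had a slope of 1.61 ± 0.36, and Sox17 and Foxa2, transcription factor genes of the endoderm, 1.36 ± 0.24 and 1.10 ± 0.27. The streak genes T (Brachyury) and Wnt8a had 1.53 ± 0.58 and 1.49 ± 0.28. The adjusted p-values of these 5 genes ran from 0.0796 to 0.366.

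Weaker list results were mesoderm (16 genes, 5 higher adjusted over the list alone, median 0.23, adjusted p = 2.9e-04) and epithelial-mesenchymal transition (16 genes, 2 higher and 1 lower, 0.32, 0.00305). In the same terms came trophoblast (10 genes, 2 higher, 0.50, 0.00221), extraembryonic endoderm (17 genes, 3 lower, −0.29, 0.00221) and ribosomal proteins (79 genes, 0 higher or lower, 0.18, 0.0281). With an estimated correlation none of these held (adjusted p = 0.205, 0.0834, 0.205, 0.159 and 0.656 with an estimated correlation). The epithelial-mesenchymal list holds both epithelial and mesenchymal genes, so its median gives no direction of a transition. Without SFM replicate 2, the epithelial genes Esrp1 and Epcam had slopes of 0.72 and 0.69. The mesenchymal genes Snai1 and Zeb2 had 0.73 and −0.47. The epithelial-mesenchymal list reached 0.0670 without SFM replicate 1, and the ribosomal protein median was 0.007 without SFM replicate 2 (adjusted p = 0.870). Hand1 and Kdr, genes of the extraembryonic and flank mesoderm and of blood and endothelial precursors, had slopes of 1.16 ± 0.17 and 1.07 ± 0.20, and Tdgf1, the gene of the Nodal co-receptor Cripto, 1.15 ± 0.17. Their adjusted p-values were 0.0539, 0.0917 and 0.0551. No call was made for blood and endothelium (adjusted p = 0.340), housekeeping (0.350), p53 targets (0.176), pluripotency and epiblast (0.488; 4 of 22 members higher and 3 lower adjusted over the list alone), proliferation (0.603) or stress and immediate early genes (0.488).

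**Figure D1:**
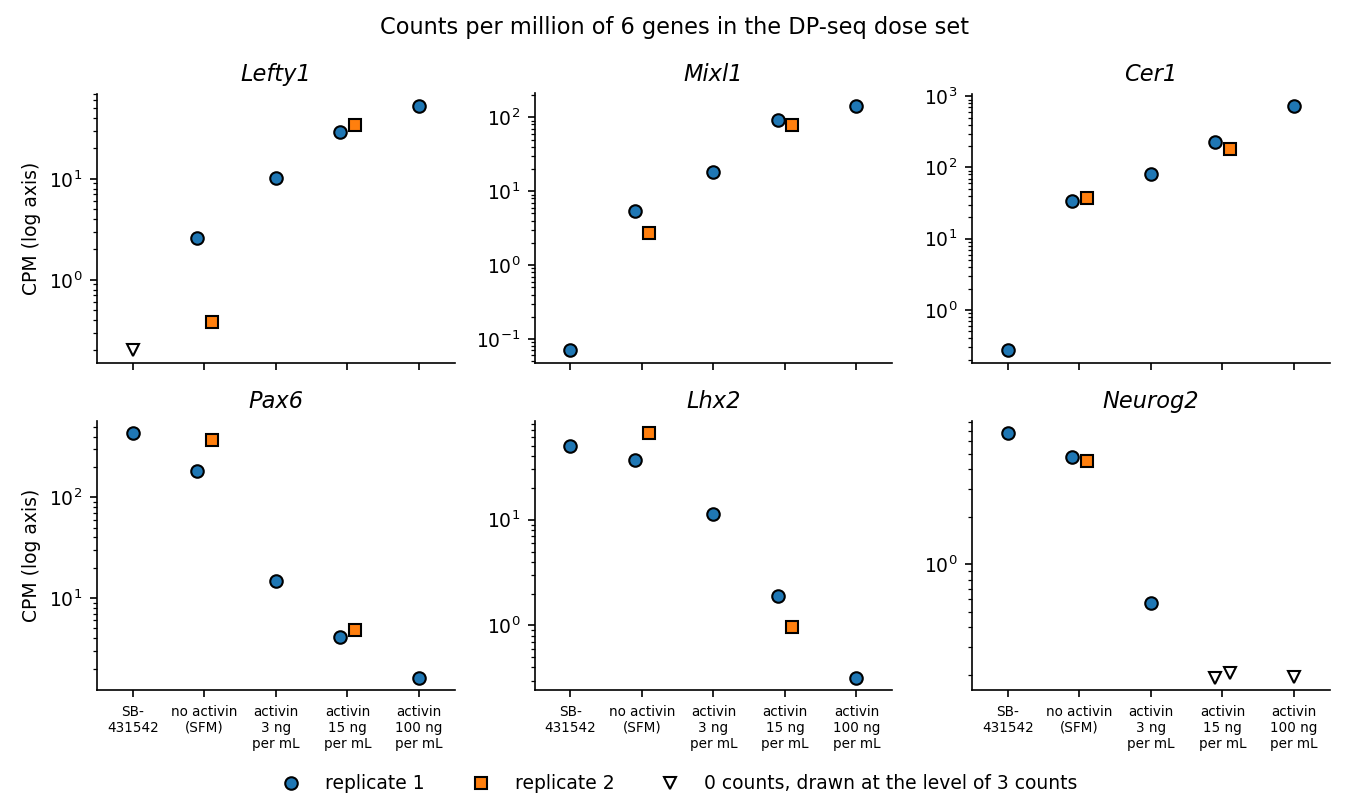
CPM (log axis) for 6 genes in each library of the dose set, by treatment. Circles are replicate 1 or the only library, squares replicate 2, and open triangles 0 counts drawn at the level of 3 counts. Mixl1, Cer1 and Lefty1 lie highest in AA100 and Pax6 and Lhx2 lowest there, while Neurog2 has 0 counts in AA15 and AA100.

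Receptor inhibition was compared with the untreated control. Lefty2 and Lefty1, paired Nodal antagonist genes that Nodal signalling switches on, had 0 counts in SB, at least 63.5-fold and at least 7.52-fold lower than in SFM. These bounds rest on both SFM libraries, which lie far apart. SFM replicate 1 alone held 80 counts of Lefty2 and 40 of Lefty1. Cer1 stood at 0.251 CPM in SB against 39.0 in SFM, Tdgf1 at 12 against 214, and Mixl1 had 1 count against 118. Fgf5, a gene of the primed epiblast, and Kdr, the VEGF receptor gene of blood and endothelial precursors, gave log2 changes of −4.44 ± 0.74 and −3.66 ± 0.77. No gene passed in edgeR (0 of 12180; smallest adjusted p = 0.963; 179 at unadjusted p under 0.05), and DESeq2 called 17. Camera placed the Activin/Nodal list (18 genes, 2 lower adjusted over the list alone, median −1.26) and the streak list (18 genes, 5 lower, median −2.74, or −1.56 with members at 0 counts set to their bound) below other genes. It did the same for the endoderm list (20 genes, 1 lower) and the pluripotency list (22 genes, 1 lower). The adjusted p-values were 1.5e-06, 1.4e-09, 1.2e-04 and 0.00132. With an estimated correlation these became adjusted p = 0.266, 0.266, 0.266 and 0.277 with an estimated correlation, and without SFM replicate 1 they were 0.212, 0.191, 0.340 and 0.377.

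The comparisons with SFM depend on both of its libraries, which lie far apart. The log2 ratio of SFM replicate 2, labelled as carrying yeast spike-ins, to SFM replicate 1 had an SD of 1.85 over genes, against 0.445 between the AA15 technical replicates. The following breakdown without SFM replicate 2 was chosen after seeing the data; the spread then comes from the AA15 pair of technical replicates alone, and each lone library is assumed to vary like the other groups. Its p-values therefore set differences between separate samples against technical spread. In that fit 498 genes passed in SB, 637 in AA3, 1570 in AA15 and 1560 in AA100, and without SFM replicate 1 instead 7055, 6921, 7815 and 7156. In SB, Lefty2 (0 against 80 counts, adjusted p = 4.2e-12), Lefty1 (0 against 40, 2.3e-07), Tdgf1 (log2 change −4.11 ± 0.33, 1.9e-22) and Cer1 (−6.90 ± 0.49, 3.1e-26) were then called lower. So were 7 of 18 Activin/Nodal genes, 8 of 20 endoderm genes, 6 of 17 streak genes and 7 of 22 pluripotency genes, while 1 pluripotency gene and no other member of these lists was higher. The camera adjusted p-values were 4.8e-08, 4.8e-08, 7.0e-09 and 4.6e-09, and none held (adjusted p = 0.445 with an estimated correlation).

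At 3 ng/mL, Pmepa1 gave a log2 change of 3.37 ± 0.71 from SFM, Nodal 3.28 ± 0.92 and Lefty1 2.79 ± 0.94, while Pax6 gave −4.45 ± 1.06 and Pou5f1, the pluripotency gene that encodes Oct4, 2.27 ± 0.68. None passed in edgeR over all libraries (0 of 12180; smallest adjusted p = 0.985; 197 at unadjusted p under 0.05; 14 with DESeq2). The Activin/Nodal list lay higher (18 genes, 0 past the test adjusted over the list alone, median 1.05, camera adjusted p = 1.4e-04; adjusted p = 0.410 with an estimated correlation), and 0.219 without SFM replicate 1. Without SFM replicate 2, Nodal (2.66 ± 0.51, adjusted p = 8.9e-05), Lefty1 (2.09 ± 0.38, 2.2e-05) and Pou5f1 (1.84 ± 0.29) were called higher and Pax6 lower (−3.54 ± 0.32, 7.8e-19). In that fit, 8 of the Activin/Nodal genes were higher and 0 lower, and 11 of 27 neuroectoderm genes were lower and 1 higher. Camera gave adjusted p-values of 4.5e-05 and 5.5e-07 (adjusted p = 0.543 with an estimated correlation for both).

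At 15 ng/mL, Lefty1, Nodal and Mixl1 gave log2 changes of 4.43 ± 0.90, 4.39 ± 0.87 and 4.33 ± 0.55, Gsc 3.75 ± 1.15, Cer1 2.38 ± 0.56, Tdgf1 2.62 ± 0.59 and Pou5f1 2.68 ± 0.61. Pax6, Lhx2 and Tubb3, the neuronal β-tubulin gene, gave −6.16 ± 0.84, −5.36 ± 0.82 and −4.60 ± 0.93. In edgeR 0 of 12180 genes passed (smallest adjusted p = 0.635; 702 at unadjusted p under 0.05), and DESeq2 called 166. Adjusted over the list alone, 6 of 18 Activin/Nodal genes and 3 of 18 streak genes were higher and 11 of 27 neuroectoderm genes lower. Camera gave adjusted p-values of 3.3e-06, 5.1e-08 and 9.0e-09 (adjusted p = 0.285, 0.285 and 0.300 with an estimated correlation). Without SFM replicate 1 the Activin/Nodal and neuroectoderm lists reached 0.0556 and 0.0561. Without SFM replicate 2, Mixl1 (4.11 ± 0.32, adjusted p = 7.6e-24), Lefty1 (3.75 ± 0.35, 6.3e-18) and Nodal (3.77 ± 0.46, 3.9e-11) were called higher and Pax6 (−5.23 ± 0.26, 1.6e-42) and Lhx2 (−4.52 ± 0.32, 2.8e-27) lower. In that fit 10 Activin/Nodal genes were higher and 2 lower, and 17 neuroectoderm genes were lower and 2 higher.

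At 100 ng/mL, Sox17 gave a log2 change of 4.31 ± 0.97, Cer1 4.21 ± 0.65, Gsc 4.68 ± 1.27, Mixl1 5.08 ± 0.60, Lefty1 5.15 ± 0.99 and Pmepa1 4.30 ± 0.71. The mesoderm genes Hand1 and Kdr gave 3.68 ± 0.64 and 3.59 ± 0.60. Pax6 and Lhx2 gave −7.63 ± 1.25 and −7.49 ± 1.27. In edgeR 0 of 12180 genes passed (smallest adjusted p = 0.818; 541 at unadjusted p under 0.05), and DESeq2 called 104. Adjusted over the list alone, 7 of 18 streak genes, 1 of 20 endoderm genes, 5 of 18 Activin/Nodal genes and 3 of 17 mesoderm genes were higher and 6 of 27 neuroectoderm genes lower. Camera gave adjusted p-values of 7.7e-15, 1.7e-15, 1.7e-10, 2.8e-05 and 7.4e-10. With an estimated correlation these were adjusted p = 0.0974, 0.0974, 0.154, 0.154 and 0.176 with an estimated correlation, and the mesoderm list gave 0.222 without SFM replicate 1. Without SFM replicate 2, Mixl1 (4.84 ± 0.35, adjusted p = 7.4e-27), Cer1 (4.55 ± 0.33, 7.4e-27), Kdr (3.97 ± 0.35, 2.5e-20), Sox17 (3.62 ± 0.55, 2.4e-08) and Hand1 (3.95 ± 0.57, 4.4e-09) were called higher. In that fit 17 of the endoderm genes were higher and 0 lower, and 17 neuroectoderm genes were lower and 1 higher.

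AA100 and AA3 were compared within each library method. In standard RNA-seq, Sfrp5, a secreted Wnt antagonist gene of the anterior endoderm, was at 1.5 ± 0.629 CPM (SD, n = 2) in AA3 and 60.4 in AA100 (log2 change 5.31 ± 0.15, adjusted p = 1.1e-251). Hnf4a, a transcription factor gene of the endoderm, gave 4.27 ± 0.28, Hhex, a homeobox gene of the anterior endoderm, 1.74 ± 0.06, and Lefty1 2.80 ± 0.10 (10.3 to 71.3 CPM). Lower in AA100 were Aldh1a2, the retinoic acid synthesis gene (−4.32 ± 0.37, adjusted p = 2.7e-29), Foxc1, a forkhead gene of the mesoderm (−3.13 ± 0.22), and Fn1, the fibronectin gene (1131 to 369 CPM). T gave −0.25 ± 0.02, Mixl1 0.53 ± 0.07, Nanog, a pluripotency gene, 0.86 ± 0.11, Utf1, an embryonic stem cell chromatin gene, 2.13 ± 0.06 and Pmepa1 2.62 ± 0.09. The other large calls were Tuba8, an α-tubulin gene (5.27 ± 0.22), Pga5, a pepsinogen gene (4.05 ± 0.09), and Shisa3, a Wnt and FGF receptor modulator gene (3.49 ± 0.44), higher. Also lower were Rn28s1, the 28S ribosomal RNA (−5.67 ± 0.02), Klhl6 (−3.66 ± 0.42), Amhr2 (3 against 117 counts) and Mir703 (3 against 101).

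In that comparison 3926 genes rose and 3923 fell of 12605 (edgeR), 839 and 813 of them by at least 2-fold. The AA3 pair differed by little more than counting noise (chi-square 1.29 per degree of freedom, against 31.2 for the AA15 pair), so that the test compares these libraries, not the conditions. In a joint fit with the other methods 269 genes passed, and in that fit 47 without AA3 replicate 1 and 53 without AA3 replicate 2, with the lone libraries assumed to vary like the other groups. Of the endoderm list 13 of 20 rose and 5 fell (camera adjusted p = 1.6e-06) and of Activin/Nodal genes 12 of 20 rose and 2 fell (0.00187). Of mesoderm genes 2 of 18 rose and 12 fell (0.00493), and of ribosomal protein genes 23 of 81 rose and 53 fell (2.6e-11), among them Rpl39, which fell by 2.65. Adjusted over the list alone the counts were the same but for 54 ribosomal protein genes lower. Pluripotency (10 of 19 rose, 5 fell; 11 and 5 adjusted over the list alone) and trophoblast (3 of 8 rose, 4 fell, also over the list alone) both had 0.0466. They had 0.0781 and 0.207 without AA3 replicate 1 and 0.109 and 0.334 without AA3 replicate 2. None held, each at adjusted p = 0.574 with an estimated correlation.

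In DP-seq from 50 pg, Cer1 rose from 325 to 2095 ± 310 CPM (SD, n = 2) between AA3 and AA100 (log2 change 2.69 ± 0.20, adjusted p = 7.6e-09), and Lefty1 from 6.5 to 73.8 ± 12.6 CPM (3.50 ± 0.48, 6.1e-05). Smad7, an inhibitory Smad gene of TGF-β signalling (4.52 ± 0.85), and Foxa3, a forkhead gene of the endoderm (2.57 ± 0.58), also rose. Mesp1, a cardiac mesoderm transcription factor gene, had 0 counts in AA100, at least 60.2-fold lower. In the dose set it went the other way, with 11 counts in AA3 and 116 in AA100. Dll1, a Notch ligand gene of the presomitic mesoderm, Foxc1 and Fn1 fell, with log2 changes of −6.37 ± 1.04, −5.47 ± 1.26 and −2.06 ± 0.30. Genes at 0 counts in AA3 included Adgrg1, an adhesion G protein-coupled receptor gene (at least 56.3-fold higher in AA100), Tuba8 (at least 36.2-fold), Syp, the synaptophysin gene (at least 30.2-fold), Rhbdd3 (at least 29.2-fold) and Klhl10 (at least 27.7-fold). AA3 is a single library here, and these bounds cover counting error only. Of the 10389 genes used for replicate spread, 290 had 0 counts in 1 of the 2 AA100 libraries. A 0 in 1 library therefore need not mean absence from the sample. Zkscan7, Scrt2 and Lancl3 had 1, 1 and 2 counts in AA100 against 87, 80 and 106 in AA3. Utf1 (3.92 ± 1.46), T (−0.50 ± 0.21), Mixl1 (−0.27 ± 0.43) and Nanog (0.11 ± 0.43) did not pass. Mixl1 gave 0.20 without AA100 replicate 1 and Nanog −0.07 without AA100 replicate 2.

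Over all genes in that comparison 264 rose and 135 fell of 11631 (edgeR). In the joint fit of the methods 330 passed, and in that fit 519 and 505 without AA100 replicate 1 or 2, 139 and 144 of them among those 399. With the 50 pg AA3 libraries of the dilution series added 54 passed. Of 18 Activin/Nodal genes 3 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.00189, or 0.118 without AA100 replicate 1). Of 20 endoderm genes 4 rose and 1 fell (5 and 1; 0.00308). Of 17 mesoderm genes 0 rose and 3 fell (0 and 4; 1.0e-04), and of 19 pluripotency genes 3 rose and 0 fell (5 and 0; 0.0135). Of 78 ribosomal protein genes 0 rose and 8 fell (1 and 12; 1.9e-05). None held, each at adjusted p = 0.822 with an estimated correlation.

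In SMART-seq from 50 pg, Cer1 rose from 170 ± 12.3 to 1109 ± 46.9 CPM (SD, n = 2 each; log2 change 2.71 ± 0.09, adjusted p = 0.00115) and Lefty1 from 9.70 ± 3.53 to 149 ± 8.68 CPM (3.94 ± 0.30, 0.0137). Utf1 (3.33 ± 0.26), Grn, the granulin precursor gene (4.32 ± 0.29), Pga5 (4.01 ± 0.19), Bhlhe40, a basic helix-loop-helix repressor gene (3.41 ± 0.36), and Rpl14, a ribosomal protein gene (1.80 ± 0.04), rose as well. T (−1.26 ± 0.15) and Fn1 (−2.01 ± 0.21) fell, as did Foxb1, a neural forkhead gene (−5.89 ± 0.82), Yy2, a zinc finger gene (−5.86 ± 0.60), and Car3, a carbonic anhydrase gene (−3.52 ± 0.42). Alx1, a craniofacial mesenchyme homeobox gene, and Pcdh18, a protocadherin gene, had 1 and 3 counts in AA100 against 677 and 571 in AA3. Foxc1 (−4.60 ± 0.73, adjusted p = 0.0571), Nanog (2.08 ± 0.36, 0.0680) and Mixl1 (0.36 ± 0.21, 0.482) did not pass. In all 90 genes rose and 65 fell of 11453 (edgeR), against 1193 called by DESeq2, 573 in the joint fit of the methods and 250 without the filter on low counts. In edgeR 18 passed without AA3 replicate 1, 18 without AA3 replicate 2, 12 without AA100 replicate 1 and 11 without AA100 replicate 2.

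Among the lists in that comparison, 2 of 16 Activin/Nodal genes rose and 0 fell (4 and 1 adjusted over the list alone). Of 20 endoderm genes 3 rose (4 over the list alone; median 0.05) and of 18 pluripotency genes 2 rose (5). Each of these lists had a camera adjusted p of 1.0e-04. Of 12 mesoderm genes 0 passed over all genes and 4 were lower over the list alone (8.1e-04), and of 82 ribosomal protein genes 3 rose and 11 fell (4 and 47; 2.7e-05). Neuroectoderm (18 genes, 2 lower over the list alone) had 0.0159, p53 targets (15 genes, 3 higher) 0.0244 and stress and immediate early genes (16 genes, 6 higher) 0.0232. None held (adjusted p = 0.315 with an estimated correlation, 0.349 for stress genes and 0.647 for ribosomal proteins). The endoderm list lost its call without AA3 replicate 2 (median −0.03, adjusted p = 0.154) or AA100 replicate 2 (0.135). Neuroectoderm and p53 targets lost theirs without AA3 replicate 1 (0.0516 and 0.107) or AA100 replicate 1 (0.0512 and 0.158), and stress genes without AA3 replicate 2 (0.0922) or AA100 replicate 1 (0.119).

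**Figure D2:**
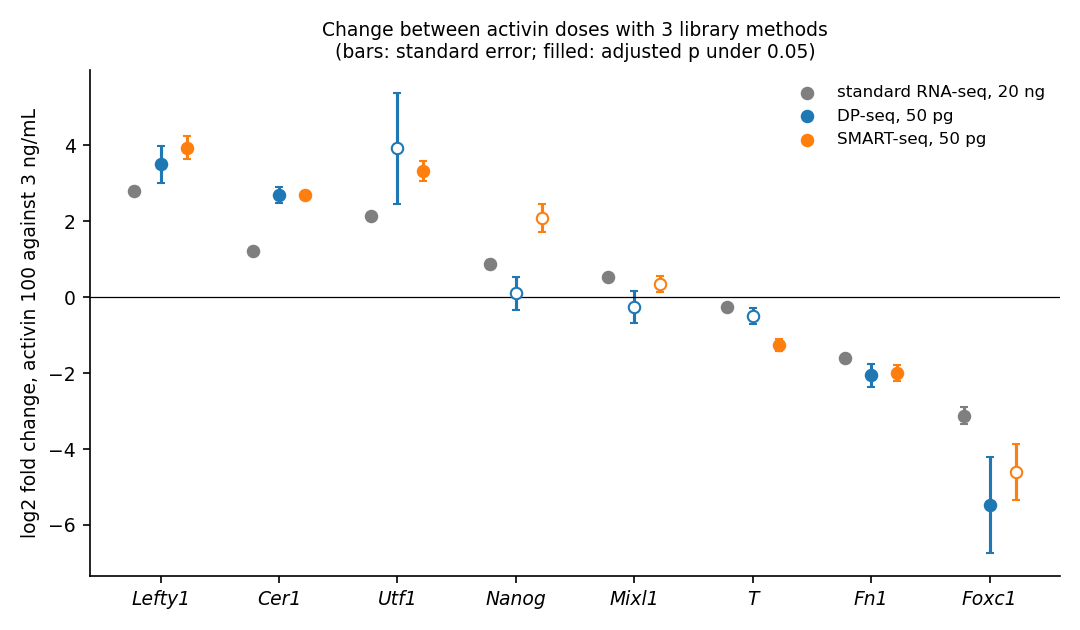
Log2 fold change between AA100 and AA3 (vertical axis, bars are the standard error) for 8 genes with standard RNA-seq, DP-seq and SMART-seq; filled points passed an adjusted p of 0.05. Lefty1 and Cer1 lie above 0 with a filled point for each method, and Fn1 below 0.

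Whether the change differed between methods was tested directly in 1 joint fit of 14072 genes. Gapdh, the glycolytic enzyme gene often used as a reference, gave 2.33 ± 0.04 in standard RNA-seq (85.9 to 432 CPM), with a difference of −2.19 ± 0.10 for DP-seq and −2.54 ± 0.10 for SMART-seq. Rps26, a ribosomal protein gene, gave 3.03 ± 0.02 in standard RNA-seq (135 to 1100 CPM), with differences of −3.49 ± 0.16 for DP-seq and −3.27 ± 0.13 for SMART-seq. Tuba1b, an α-tubulin gene, went the other way, at −2.31 ± 0.06 in standard RNA-seq (218 to 43.7 CPM) and differences of 2.52 ± 0.16 and 1.90 ± 0.14, as did Rpl14 with 1.64 ± 0.09 and 2.09 ± 0.08. Pou5f1 (2.04 ± 0.17) and Npm1, the nucleophosmin gene (−1.12), differed between DP-seq and standard RNA-seq, and Rpl23 (−1.13 ± 0.08) and Ranbp1, a Ran binding protein gene (−2.03), between SMART-seq and standard RNA-seq. Near-identical copies exist for several of these genes, so their values are uncertain. The difference passed for 104 genes for DP-seq (47 more positive and 57 more negative than standard RNA-seq; 30 and 65 with DESeq2 size factors) and for 120 for SMART-seq (35 and 85).

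Between DP-seq and SMART-seq 3 genes differed, Actg1, the cytoplasmic γ-actin gene (−1.10, adjusted p = 0.0181), Psmb3, a proteasome subunit gene (1.47, 0.0181), and Sae1, a SUMO activating enzyme gene (1.18, 0.0306), named here after their values were seen. With 1 standard AA3 library left out, the DP-seq count was 5 (without replicate 1) or 9 (without replicate 2) and the SMART-seq count 9 or 11. Without DP-seq AA100 replicate 1 or 2 the DP-seq count was 291 or 225. The SMART-seq count was 9 and 8 without SMART-seq AA3 replicate 1 and 2, and 12 and 18 without SMART-seq AA100 replicate 1 and 2. For DP-seq against SMART-seq it was 65 without DP-seq AA100 replicate 2 and 6 without replicate 1. It was 0 with any 1 SMART-seq library left out in edgeR (1957 and 2009 at unadjusted p under 0.05 without AA3 replicates 1 and 2, 2178 and 2195 without AA100 replicates 1 and 2). DESeq2 called 549 over all libraries.

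Across 9493 genes, which are not independent replicates, the log2 changes of standard RNA-seq had a Pearson correlation of 0.301 with those of DP-seq from 50 pg (Spearman's rho 0.273) and 0.316 with those of SMART-seq (0.294). Between DP-seq and SMART-seq it was 0.254 (0.277). Of 863 genes changed at least 2-fold in standard RNA-seq, 76.1% had the same direction in DP-seq and 79.6% in SMART-seq. Against AA100 and AA3 of the dose set, the correlations were 0.036 for standard RNA-seq, 0.019 for DP-seq from 50 pg and 0.01 for SMART-seq, and 53.4% of those 863 genes had the same direction. By list median, mesoderm genes lay higher in AA100 than in AA3 of the dose set but lower in the method set. The median log2 change from SFM was −0.22 in AA3 and 0.69 in AA100. Between AA3 and AA100 it was −1.55 in standard RNA-seq, −2.12 in DP-seq from 50 pg and −1.70 in SMART-seq.

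The dilution series asked how little mRNA suffices. At 100 pg against 10 ng, Tln1, the gene of the adhesion protein talin 1, rose from 10.4 to 400 CPM (log2 change 5.26 ± 0.38, adjusted p = 3.1e-04). Dicer1, the microRNA processing enzyme gene, Tbca, a tubulin folding cofactor gene, Chchd1, a mitochondrial ribosome gene, and H3f3a, a replacement histone gene, rose by 3.54 ± 0.42, 2.84 ± 0.29, 2.83 ± 0.19 and 2.81 ± 0.53. Calr, the calreticulin gene (−1.87 ± 0.24), Nono, an RNA-binding protein gene (−1.74 ± 0.24), Top3b, a topoisomerase gene (−2.76 ± 0.51), Ipo11, an importin gene (−2.34), and Pfkl, a phosphofructokinase gene (−2.30), fell. Tln1 remained called at each lower amount, at 4.60 ± 0.37 for 50 pg, 8.59 ± 0.44 for 10 pg and 10.29 ± 0.47 for 1 pg. Dicer1 was also called at each, at 3.22 for 50 pg, 6.91 ± 0.49 for 10 pg and 9.4 ± 0.55 for 1 pg. Prss2, a trypsinogen gene, gave 5.39 ± 0.82, 8.31 and 10.24 at 50, 10 and 1 pg. Other called rises were Yy1, a zinc finger transcription factor gene (3.33), and Chchd2 (3.20) at 50 pg, and Trappc13 (5.4) and Egfr, the EGF receptor gene (5.27), at 10 pg. At 1 pg they were Upk1b (10.54), Rapgefl1 (10.41) and Prss43 (1 count at 10 ng). At 1 pg these genes stood at 349 ± 484, 782 ± 1096 and 174 ± 219 CPM (SD, n = 2), so that most counts came from 1 library. The same held for Egfr at 10 pg, with 828 ± 1112 CPM (SD, n = 2).

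Other genes had no counts left at a smaller input. Strn, the striatin gene, had 0 counts at 50 pg (at least 28.8-fold lower). So had Tmem198b, Coro2b, Ttc9, Atn1 and Txnrd3 at 10 pg (at least 43.8-, 33.7-, 33.2-, 32.3- and 32.2-fold). At 1 pg Dpf2, Litaf, Prpf39, Fancd2 and Ttc1 had 0 counts (at least 22.8-, 22.8-, 21.1-, 21- and 14.9-fold). At 50 pg Fam234a had 1 count against 100, and Cnot3, Man1b1 and Top3b gave −3.50, −3.09 and −2.90. In edgeR 0 of 10817 genes passed at 1 ng against 10 ng (136 at unadjusted p under 0.05; 77 with DESeq2). At 100 pg 98 rose and 9 fell, at 50 pg 100 and 17, at 10 pg 382 and 523, and at 1 pg 969 and 1721. DESeq2 called 1246, 1274 and 2844 genes at 100, 50 and 10 pg. Fits of only the 2 amounts, which take the spread from those 4 libraries, called 1617 at 1 ng, 3966 at 100 pg, 2863 at 50 pg, 249 at 10 pg and 0 at 1 pg in edgeR (2818 at unadjusted p under 0.05; 3457 with DESeq2 over all amounts). The counts therefore do not rank the amounts. After thinning to equal totals 239 passed at 10 pg, and with the replicate number as a block 63, 66 and 397 at 100, 50 and 10 pg. DESeq2 size factors shifted the median of all genes from 0 to −0.14 at 100 pg, from −0.03 to −0.19 at 50 pg, from −0.12 to −0.30 at 10 pg and from −1.43 to −1.12 at 1 pg. With them the counts higher and lower were 306 and 679 at 10 pg and 1174 and 1331 at 1 pg. Leaving out 10 ng replicate 1 or 2 gave 10 and 14 genes at 100 pg, 12 and 13 at 50 pg, 39 and 33 at 10 pg and 1027 and 923 at 1 pg. Leaving out replicate 1 or 2 of the smaller input gave 15 and 12, 16 and 14, 1774 and 1558, and 3921 and 3412.

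By list test, ribosomal protein genes lay higher than other genes at low input in the dilution series. Their share of all counts went from 7.33% at 10 ng to 8.97%, 8.65% and 8.42% at 100, 50 and 10 pg, but at 1 pg it was lower, at 6.21% (7.50% against 7.89% without the 10 most counted other genes). The AA3 library of the method set made from 50 pg had 6.92%, below the 10 ng libraries. At 100 pg 7 of 78 rose and 0 fell (25 rose adjusted over the list alone), with a median log2 change of 0.86 (0.72 with DESeq2 size factors) and a camera adjusted p of 5.4e-14 (adjusted p = 0.00205 with an estimated correlation). The medians were 0.49, 0.82 and 0.38 at 50, 10 and 1 pg (0.33, 0.65 and 0.69 with DESeq2 size factors). There were 4, 17 and 24 genes higher (13, 27 and 24 adjusted over the list alone), and 4 fell at 1 pg. The camera adjusted p-values were 1.4e-07, 1.3e-11 and 4.4e-05 (adjusted p = 0.0125, 0.00352 and 0.0369 with an estimated correlation). At 1 ng the median was 0.19 (adjusted p = 0.0496; adjusted p = 0.316 with an estimated correlation). The p was 0.0835 without 1 ng replicate 2, 0.159 without 10 ng replicate 1 and 0.106 without 10 ng replicate 2.

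After thinning every library to 427556 counts, 10174.5 ± 50.2 genes (SD, n = 2) had at least 1 count at 10 ng and 10281 ± 69.3 at 1 ng. The number was 9422 ± 86.3 at 100 pg, 9070.5 ± 41.7 at 50 pg, 7886.5 ± 53 at 10 pg and 6418 ± 102 at 1 pg. The SD over genes of the log2 ratio of the replicates was 0.432, 0.365, 0.732, 0.95, 1.78 and 3.21 in the same order. It was 0.237 for standard RNA-seq, 1.31 and 1.38 for SMART-seq AA3 and AA100 and 1.23 for DP-seq AA100 from 50 pg. Across genes, the replicates correlated at 0.983 at 10 ng and 0.163 at 1 pg. Dicer1 alone took 10.5% and 4.21% of the counts of the 1 pg libraries.

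**Figure D3:**
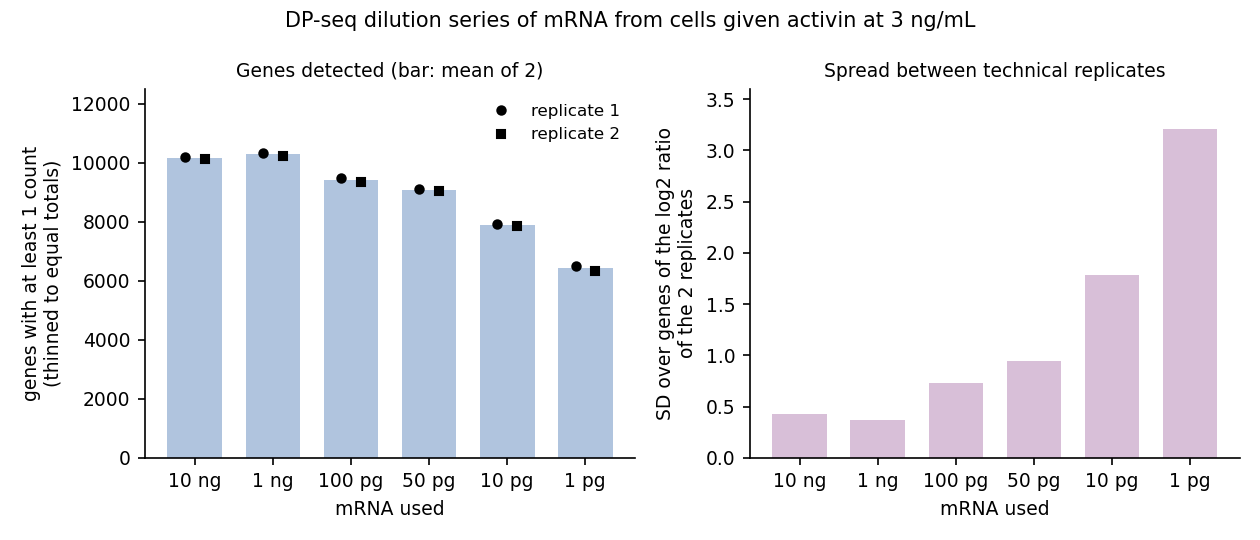
Left, genes with at least 1 count after thinning to equal totals (bars are means of 2 libraries, points the libraries); right, SD over genes of the log2 ratio of the 2 replicates; both against the mRNA used. Detection falls from 10174.5 genes at 10 ng to 6418 at 1 pg and the SD rises from 0.432 to 3.21.

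Primer sets 1, 2 and 3 were designed to suppress ribosomal transcripts. Each library was compared with the mean of the 1 ng and 100 pg libraries of the dilution series (2 each). The labels of those libraries do not name their primer collection. Ribosomal protein genes took 3.25% of the counts with set 1 (Wilson 95% interval 3.23 to 3.26), 2.91% with set 2 (2.90 to 2.93) and 2.38% with set 3 (2.36 to 2.39). The share was 7.15% and 7.12% in the 1 ng libraries, 9.24% and 8.71% at 100 pg and 6.09% in the paired-end library. The method set's DP-seq libraries from 50 pg, labelled as made with the original primers, had 6.92% for AA3 and a mean of 5.80% for AA100. In standard RNA-seq the share was 7.67%, 7.67% and 6.88%, and in SMART-seq 24.6% to 27.4%. Of 81 ribosomal protein genes, 51 fell and 17 rose with set 1, 44 and 20 with set 2 and 54 and 16 with set 3. Adjusted over the list alone the counts were 51 and 17, 45 and 20, and 55 and 16. Rps19 gave a log2 change of −8.54 with set 1 and had 2 counts with set 2. Rpl30 had 0 counts with set 1 (at least 25.1-fold lower) and Rps25 gave −8.88 with set 3. In contrast, Rpl26 gave 9.70 with set 2 and Rpl38 13.28 with set 3. The median changes were −1.64, −1.69 and −2.31, or −1.52, −1.16 and −1.81 with genes at 0 counts set to their bound, and −1.56, −1.50 and −2.11 with DESeq2 size factors. Camera gave adjusted p-values of 6.0e-06, 1.2e-04 and 4.3e-06 (adjusted p = 0.295, 0.378 and 0.324 with an estimated correlation). The set 2 list gave 0.0593 without 1 ng replicate 2.

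Other genes moved as well. With set 1, Keap1, the gene of an oxidative stress sensor (8.74 ± 0.48), Ano8 (7.97 ± 0.32) and Slain2 (7.76) rose, and Mapk8ip3 and Snora31 had 105 and 57 counts against 2 each. Ndufa3, a respiratory complex I gene, fell (−9.54 ± 0.29, adjusted p = 1.2e-07), as did Arl6 (1 against 2956 counts) and Atp5j, Exosc8 and Chuk (0 counts; at least 29.5-, 28.2- and 18.7-fold). With set 2, Eomes, a T-box gene of the streak (9.41 ± 0.20, 8.1e-09), Kctd9 (9.27), Zbtb44 (at least 181-fold), Wdr36 (219 against 3 counts) and Rap1gds1 (159 against 2) were higher. Txn1, the thioredoxin gene, Coa3, Mxra8, Naa38 and Rwdd1 had 0 counts (at least 641-, 292-, 182-, 118- and 98.2-fold lower). With set 3, Lrrc47 (10.11 ± 0.28, 2.5e-08), Peg13 (9.26), Gucy1b1 (at least 356-fold), Aimp2 (918 against 2 counts) and Snord14a (135 against 2) were higher. Uqcrq, a respiratory complex III gene, Snhg6, Sem1, Pex14 and Bax, a proapoptotic gene, had 0 counts (at least 391-, 167-, 116-, 115- and 101-fold lower). Gapdh gave −8.45 with set 2 and −6.87 with set 3. Of 11559 genes 3261 rose and 3253 fell with set 1, 3399 and 3983 with set 2 and 3318 and 3799 with set 3 (edgeR; each primer set library is assumed to vary like the 1 ng and 100 pg pairs). The median of all genes stood at −0.04, −0.43 and −0.40. DESeq2 size factors moved these medians to 0.04, −0.23 and −0.21. In set 1 the pluripotency list (11 of 17 rose, 1 fell; 12 and 1 adjusted over the list alone) and the housekeeping list (2 of 15 rose, 11 fell, also over the list alone) were also called. Camera gave adjusted p-values of 0.00693 and 0.0287 (adjusted p = 0.551 and 0.646 with an estimated correlation).

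**Figure D4:**
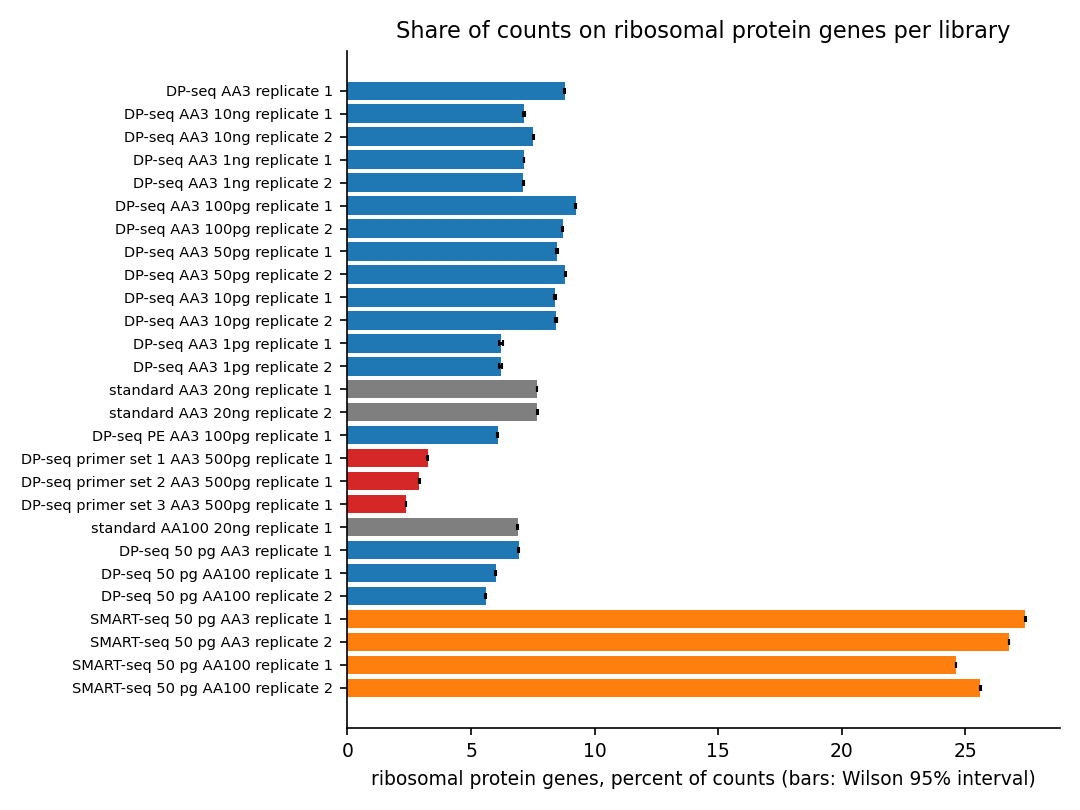
Percent of counts on ribosomal protein genes in each library (bars start at 0; error bars are Wilson 95% intervals), by method, input and primer set. The 3 primer set libraries lie between 2.38% and 3.25% and the SMART-seq libraries between 24.6% and 27.4%.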

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

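Of the tests weighed here, the one on 28S ribosomal RNA was chosen only after the result was seen. In a joint fit, the change between AA100 and AA3 differed between DP-seq and standard RNA-seq for 104 genes, between SMART-seq and standard RNA-seq for 120, and between DP-seq and SMART-seq for 3. The genes that differ from standard RNA-seq include abundant ones with many copies in the genome, such as Gapdh, Rps26, Rpl14, Tuba1b and Npm1.

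For the SMART-seq difference, reads shared with copies of a gene were weighed against 28S ribosomal RNA left in the standard AA3 libraries. For the latter, 28S took at most 1.47% of the counts of those libraries. These are unique read counts, so its share of all reads is unknown if reads that match several places were left out. The share therefore cannot decide on 28S as an explanation. Shared sequence stays open and may account for part of the pattern: the 116 called genes with a reference transcript shared a median of 6.96% of their 32-base words with another gene, above 99.9% of 10000 matched lists (median 1.96%), whereas genes called between AA100 and AA3 in SMART-seq itself lay at percentile 46.66. The same measure lay at percentile 99.76 for the DP-seq difference. Both differences are taken from the same standard RNA-seq libraries, so this is not separate support. A real difference in dose response between RNA preparations of the methods was not tested.

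The paired-end DP-seq library, which entered no test for changed genes, had more than 3 counts for 10553 genes.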

How the results depend on the processing

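The crossed replicate block was chosen after seeing the data; the other alternatives were planned. Over list results 470 alternatives kept direction and side of the threshold, 77 lost the call and 3 turned in the direction camera gives, of which 2 kept the sign of their median; over named genes 1483 kept both, 369 lost the call, 142 gained one and 3 reversed. The cause of each move below was not tested, except where fewer libraries or genes were used. The 1 pg libraries had the lowest depth, at 427556 and 448933 counts.

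The trend count of 48 became 469 with DESeq2, 196 with SB as the lowest step, 18 with log2 of dose plus 1 and 0 to 693 with 1 library left out. The counts of 0 against SFM for SB, AA3, AA15 and AA100 became 17, 14, 166 and 104 with DESeq2, and ranged from 0 to 7055, 6921, 7815 and 7156 with 1 library left out. Without the filter on low counts the trend gave 72. Standard RNA-seq (7849) gave 4434 with DESeq2, 269 in the joint fit and, in that fit, 47 to 53 with 1 library left out. DP-seq (399) gave 54 with the dilution AA3 libraries added, and SMART-seq (155) 250 without the filter, 1193 with DESeq2, 573 in the joint fit and 11 to 18 with 1 library left out. The differences between methods (104, 120 and 3) gave 535, 484 and 549 with DESeq2, 5 to 291, 8 to 18 and 0 to 65 with 1 library left out, and 1 with DESeq2 size factors for the last.

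Same-numbered libraries did not deviate together in SMART-seq (correlation −0.014), the dilution series (a median of −0.004) or standard RNA-seq with DP-seq (0.001). The numbers therefore do not pair those libraries. In the dose set the correlation between SFM and AA15 was −0.268 over 8848 genes, so that equal numbers tended to deviate in opposite directions. A pairing of opposite numbers is not excluded there. The replicate block gave 0 trend genes, 193 for standard RNA-seq and 213 for DP-seq in the joint fit, 54 for SMART-seq, 26 and 49 for the DP-seq and SMART-seq differences from standard RNA-seq, and 63, 66 and 397 at 100, 50 and 10 pg. The crossed block gave 1 trend gene and 5 genes for AA15.

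In the dilution series DESeq2 gave 77, 1246, 1274 and 2844 genes at 1 ng, 100 pg, 50 pg and 10 pg. Fits of only the 2 amounts gave 1617, 3966, 2863, 249 and 0 from 1 ng to 1 pg, thinning gave 239 at 10 pg, and leaving out 1 library gave 10 to 15, 12 to 16, 33 to 1774 and 923 to 3921 from 100 pg down. Genes with at least 5 counts numbered 6621.5, 6696.5, 5962.5, 5800, 5487 and 3490.5 from 10 ng to 1 pg, and at the deposited depth 13861, 14589, 12473.5, 11731.5 and 9465 had at least 1 count from 10 ng to 10 pg. Over genes with at least 50 counts the replicate SD was 0.429 at 100 pg, 0.56 at 50 pg and 0.131 for standard RNA-seq. Without the 10 most counted other genes the ribosomal protein share was 7.89%, 7.74% and 9.91% at 10 ng, 1 ng and 100 pg and 3.61%, 3.34% and 2.80% with sets 1 to 3; with all Rpl and Rps symbols it was 7.23% at 1 ng and 3.28%, 3.00% and 2.40% with the sets. The primer set counts kept within 1.5 times under the alternatives run.

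The correlation of standard RNA-seq with DP-seq was 0.262 at a minimum of 1 count and 0.27 to 0.3 with 1 library left out, and with SMART-seq 0.339 at a minimum of 50 counts, 0.288 at 1 and 0.265 to 0.315. DP-seq with SMART-seq gave 0.322 at 50 counts, 0.201 at 1, 0.235 with a prior count of 0.5 and 0.211 to 0.233. With the dose set, standard RNA-seq gave 0.043 at 50 counts; DP-seq 0.025 at 50 and at 1, 0.016 with the prior count of 0.5 and 0.017 to 0.018; SMART-seq 0.024 at 50 and 0.002 to 0.015. The ribosomal protein list without SFM replicate 2 had medians of 0.007 for the trend, −0.107 for SB and 0.01 for AA3 (adjusted p = 0.870, 0.203 and 0.479). With 1 library left out they reached 0.533, 2.06 and 2.08 at most. In DP-seq Mixl1 turned to 0.20 without AA100 replicate 1 (−0.96 without replicate 2) and 0.28 with the dilution libraries added. Nanog turned to −0.0736 without AA100 replicate 2 (0.27 without replicate 1).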

Other observations

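All tests in this part were chosen only after the result was seen. AA3 was measured in the dose set, in the dilution series, in the method set and in the paired-end library, and the lineage genes differ between the first and the rest. Against the dose set's AA3 library, the 10 ng dilution libraries had a median log2 difference of 1.96 over 20 endoderm genes (17 higher) and 2.10 over 14 mesoderm genes (12 higher), both above every one of 10000 lists matched on expression. The median was 1.39 over 13 primitive streak genes (10 higher; percentile 99.93). The paired-end library gave 1.06, 1.39 and 0.58 for these lists and the 50 pg library of the method set 1.89, 2.86 and 1.42. At 10 ng, housekeeping genes stood at −0.05 (percentile 42.29), ribosomal protein genes at 0.12 (66.85) and pluripotency genes at −0.37 (2.2). In the paired-end library the housekeeping list stood at −0.67 (percentile 1.05) and the ribosomal protein list at −1.31, below every matched list. Each of these differences is taken from the same single AA3 library of the dose set and has no replicate check there.

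An exchange of the AA3 and AA100 labels in the dose set is argued against, because the Activin/Nodal list was higher in its AA100 library (median 0.85, bootstrap interval 0.25 to 1.77; 15 of 18 higher). Library preparation and cells further along the response to activin cannot be told apart. The streak median lay at percentile 99.38 or higher both at 10 ng and in the paired-end library, and the neuroectoderm list at 1.11 or lower. In the paired-end library, however, lists with no lineage role moved too, and the same single library underlies each value. The neuroectoderm list lay at percentile 5.43 at 1 ng and 6.25 in the method set, and the Activin/Nodal list at 41.09 at 10 ng.

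SFM replicate 2 stands apart from SFM replicate 1: of 8258 genes with a mean of at least 50 counts, 980 (11.9%) were at least 8-fold apart, against 0% for the AA15 pair of technical replicates and 0.12% to 1.29% between SFM replicate 1 and the treated libraries. A separate culture with another response is argued against as the whole cause, since 15 housekeeping genes differed by a median absolute log2 ratio of 1.55, against 0.33 to 0.49 between SFM replicate 1 and the treated libraries. Low input as the whole cause is argued against. At equal depth SFM replicate 2 had 88.4% of the genes detected in replicate 1, close to 50 pg against 10 ng (88.6% or more). Among the most expressed genes, the SD of its log2 ratio was 1.86 or more against each library of the dose set, but at most 0.96 between 10 ng and 50 or 100 pg. Only 1 pg reached that SD, and it detected at most 64.0% of the genes of 10 ng. A share of low input in the difference stays open. A change of priming, reads or counting that acts per transcript may account for it: the SD among the most expressed genes was 110.8% of that among the least expressed ones, and 102.8%, 104.2% and 110.0% for the primer set libraries against 1 ng. Contrasts with 10 ng gave at most 79.3% down to 10 pg, but up to 107.1% at 1 pg. The primer set libraries detected 78.2% to 94.6% of the genes of the 1 ng libraries. This is at the deposited depth, where they held fewer counts, and cannot be set beside the percents at equal depth.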
